A study of Mus musculus with 22 samples.

How the data were processed

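Gene expression was measured by paired-end RNA sequencing of cells sorted from the lungs of wild-type C57BL/6 mice. Endothelial cells (CD31+), epithelial cells (CD326+) and immune cells (CD45+) were taken at embryonic days E16.5 and E18.5 and at postnatal days P7 and P28, except that no immune library was made at E18.5. The 22 libraries formed 11 groups of 2, each group a cell type at an age. Per the labels, libraries were made from total RNA with a tagmentation kit (Nextera XT). Mesenchymal cells, which the series description also names, were not analysed here.

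Per the submitters' processing notes, reads were aligned with TopHat2 2.0.9 to the mouse genome GRCm38 (mm10). The quantifier, the gene annotation and the strand setting of the counting were not given in the sources used here. The deposited matrix held a non-negative signal per gene and library for 24371 rows, and every library summed to 228405 in that unit. The unit before this rescaling was not stated; the values were not whole numbers and values above 1 did not rise with transcript length. Read depth could not be recovered, because no whole-read steps were found in the values, so no counting interval and no detection floor were computed. Age comparisons therefore gave no fold for a gene listed at 0. Because every library had the same total, a gene that took a large share lowered all others in that library.

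All 22 columns were matched to a sample through the names in the labels. A total of 27 rows carried 25 names that a spreadsheet had turned into dates; they made up at most 0.097% of any library and were left out, which left 24344 rows, of which 2683 were 0 in every library. The descriptions of 2 libraries carried another age than their titles, endothelial E16.5 replicate 2 and epithelial E16.5 replicate 1; both were used as E16.5, with a fit without them as an alternative. The descriptions also named 8 pools of animals, and the cell types of an age came from the same pools. In the epithelial E16.5 group, the replicate numbers were crossed against the pools.

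Group differences were tested with limma 3.58.1 (trend) in R 4.3.3 on log2(value + 1). A single model with a mean per group (11 residual degrees of freedom, 3.89 prior degrees of freedom) was fitted to the 12880 genes with a value of at least 1 in at least 2 samples. P-values were adjusted by the Benjamini-Hochberg method over all genes within a comparison, with a threshold of 0.05. There were 17 comparisons: 11 between ages within a cell type, 3 of a cell type against the mean of the other 2 at the ages all had (E16.5, P7 and P28), and 3 interactions that compared the change from E16.5 to P28 between cell types. P-values used the spread between replicates (animal pools) over all 11 groups. Other choices were named for counts, for values already on the log2 scale and for usual length-scaled units; the deposited unit was treated like the last of these.

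A total of 34 gene lists of cell identity, alveolar, airway, vascular and immune cell states, growth, stress and metabolism were tested with limma camera, with a preset correlation between genes of 0.01 and, as an alternative, with an estimated correlation. List p-values were adjusted over the lists within a comparison, and members were counted over all genes and adjusted over the list alone. The lists, comparisons, test, first alternatives and the rule for naming genes were chosen before the data were examined; which lists to describe was chosen after. Where a gene lost its call without 1 library, the library named is the one that gave the highest adjusted p; leaving out another often ended the call too. The rule named the sorting antigens Pecam1, Epcam and Ptprc, the 5 largest rises and the 5 largest falls past the threshold whose groups did not overlap and whose higher group had a mean of at least 10, and up to 4 members of each described list. Predicted genes, pseudogenes (except H2-Q5), ribosomal protein genes and list members were not named by size. Positions were looked up in the GENCODE M21 annotation of GRCm38; 503 of 513 named genes had 1 position.

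The alternatives were a pseudocount of 0.1, no filter, a filter of at least 5 in at least 2 samples, division by median-of-ratios size factors, a fit to the samples of that cell type alone, a fold change limit, leaving out each library in turn, leaving out both libraries with another age in their description, and replicate blocks by number or by pool. Values after division by size factors are called rescaled; the factors ran from 0.59 to 1.28 and were lowest in the P28 epithelial libraries (0.61 and 0.59). A further 2 alternatives were added after the data had been seen. Overlaps of called genes were set beside the number that independent lists would share. For the cell type comparisons, libraries were reassigned to cell types within pools in 100 splits.

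The test was checked on 12880 simulated genes, with 50 changed at each fold size. For endothelial P28 against E16.5 it recovered 30%, 98%, 96% and 100% of changes of log2 1, 2, 3 and 4, with 7 false calls. The epithelial fraction against the other 2 gave 92%, 100%, 100% and 100%, with 5 false calls. The endothelial minus epithelial interaction gave 2%, 84%, 94% and 98%, with 10 (6.7% of its calls). Far more genes were called in the data, so these rates need not hold there. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

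Sequencing runs followed age. The 6 libraries of E16.5 came from 1 run, the 6 libraries of P28 and epithelial P7 replicate 1 from another (7 libraries), the other P7 libraries from runs of 2 and 3 libraries, and the run of the 4 libraries of E18.5 was not given. Run and age could therefore not be told apart, except for epithelial P28 against P7, where 1 run held both P28 libraries and a P7 library. The values of 1 gene are not reported here.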

Results

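The 22 libraries covered 3 sorted fractions of the developing mouse lung over 4 ages, with 2 libraries per fraction and age. E16.5 and E18.5 precede birth, while P7 and P28 follow it. Every library had the same total of 228405 signal units, and read depth was unknown. Between 8359 and 10703 genes reached a value of 1 per library. Replicates correlated across genes with Pearson's r between 0.8981 (immune P28) and 0.9855 (epithelial E18.5); genes are not independent replicates. The 10 most abundant genes took 45.31% and 51.03% of the total in the P28 epithelial libraries, where Sftpc alone took 14.24% and 16.04% and Scgb1a1 took 10.84% and 7.31%. Rn45s, a ribosomal RNA precursor, took between 4.69% and 14.15%. Levels are means ± SD of 2 libraries (n = 2) unless stated, and log2 fold changes carry the limma standard error (SE). Beside each list, kept counts the members called in every fit that left out 1 library. For genes named by the size of an age or cell type difference, all libraries of the higher group lay above all libraries of the lower group. Near-identical gene copies share reads, so values of Ccl21c, histone, H2, haemoglobin, Ear and stefin genes are uncertain.

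The shared total shifted most genes in the fraction whose top genes grew. As deposited, the median log2 fold change of all genes was -0.15, -0.05 and -0.35 over the 3 epithelial steps and -0.59 from E16.5 to P28. It was -0.12 and -0.19 over both immune steps and -0.31 from E16.5 to P28, while the endothelial steps lay between -0.05 and 0.07. After rescaling, these medians lay between -0.08 and 0.07, and rescaled values stand beside most deposited log2 values of age comparisons where the shift exceeded 0.1. The median was 0.12 and -0.22 for endothelial and epithelial cells against the others (rescaled -0.07 and -0.03), where only the sorting antigen and counts carry rescaled values.

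The comparison of each fraction with the other 2 asked what each sort had enriched. Pecam1, which encodes CD31, stood at 75.3 ± 6.98 in 6 endothelial libraries against 3.71 ± 2.72 in 12 others (log2 difference 4.29 ± 0.23, rescaled 4.08, limma adjusted p = 4.85e-10). All 14 endothelial identity genes were higher, with a median log2 difference of 4.28 (14 adjusted over the list alone, 14 kept, camera adjusted p = 2.63e-10, or 0.156 by estimated correlation). They included Ramp2, a receptor partner for adrenomedullin (727 ± 205 against 31.1 ± 27.1) and Cdh5, the cadherin of endothelial junctions (284 ± 25.7 against 12.8 ± 11.1). The largest differences outside the lists were Sox18 (5.59 ± 0.25), Clec14a (5.44 ± 0.34), Sox7 (5.14 ± 0.28), Pcdh1 (4.93 ± 0.28) and Lyve1 (4.92 ± 0.34) on the higher side. On the lower side they were the metallothionein Mt1 (-3.47 ± 0.23), the phagocyte oxidase subunit Ncf1 (-3.15 ± 0.25), Perp (-2.90 ± 0.27), Tuba4a (-2.80 ± 0.13) and the lysosomal reductase Ifi30 (-2.78 ± 0.22).

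Lymphatic genes were part of the endothelial fraction. All 5 lymphatic markers were higher (5 adjusted over the list alone, 5 kept, median log2 difference 4.09, camera adjusted p = 6.19e-05, or 0.119 by estimated correlation), including the chemokine gene Ccl21a (477 ± 389 against 7.70 ± 8.84). Of 12 mesenchymal markers, 11 were higher as well (11 adjusted over the list alone, 11 kept, median 1.46, camera adjusted p = 0.00297, or 0.392 by estimated correlation), among them Mfap4, an elastic fibre protein (331 ± 151 against 106 ± 95.5). Over all genes, limma called 4580 higher and 2800 lower as deposited, and 2948 higher and 4039 lower after rescaling.

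In the epithelial fraction, Epcam, which encodes CD326, stood at 48.4 ± 24.5 against 8.51 ± 13.2 (log2 difference 3.04 ± 0.25, rescaled 3.29, limma adjusted p = 1.01e-07). All 14 epithelial identity genes were higher (14 adjusted over the list alone, 14 kept, median 2.78, camera adjusted p = 2.50e-11, or 0.149 by estimated correlation), led by Nkx2-1, the lung lineage transcription factor (261 ± 121 against 45.0 ± 64.3). So were 8 of 8 club and secretory genes (8 adjusted over the list alone, 8 kept, median 3.84, camera adjusted p = 1.35e-07, or 0.149 by estimated correlation), 9 of 9 ciliated genes (9 adjusted over the list alone, 9 kept, median 1.86, camera adjusted p = 1.27e-09, or 0.149 by estimated correlation) and 12 of 13 alveolar type 2 genes (12 adjusted over the list alone, 12 kept, median 3.00, camera adjusted p = 1.12e-09, or 0.149 by estimated correlation). Examples were the secretoglobin Scgb3a2 (486 ± 296 against 47.0 ± 74.0), the ciliogenesis factor Foxj1 (23.6 ± 9.91 against 3.01 ± 4.06) and surfactant protein C, Sftpc (19100 ± 14100 against 1760 ± 1840). The largest differences outside the lists were Sfta2 (3.84 ± 0.38), Bex4 (3.73 ± 0.31), the mucin Muc1 (3.68 ± 0.38), Lgi3 (3.56 ± 0.36) and the claudin Cldn3 (3.51 ± 0.32). The cytokine receptor chain Il2rg (-4.69 ± 0.27), Fxyd5 (-4.34 ± 0.19), Fgl2 (-4.05 ± 0.23), the intermediate filament Vim (-3.84 ± 0.23) and Gngt2 (-3.59 ± 0.21) were lowest. Limma called 2448 genes higher and 5648 lower, or 3473 and 3876 after rescaling.

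In the immune fraction, Ptprc, which encodes CD45, stood at 28.8 ± 16.9 against 0.104 ± 0.105 (log2 difference 4.51 ± 0.12, limma adjusted p = 3.77e-13). All 12 immune identity genes (12 adjusted over the list alone, 12 kept, median 5.38, camera adjusted p = 7.57e-14, or 0.0635 by estimated correlation), 11 of 11 macrophage and monocyte genes (11 adjusted over the list alone, 11 kept, median 3.61, camera adjusted p = 5.73e-10, or 0.176 by estimated correlation) and 10 of 10 neutrophil genes (10 adjusted over the list alone, 10 kept, median 4.61, camera adjusted p = 1.16e-08, or 0.0635 by estimated correlation) were higher. Among them were Tyrobp, an immune receptor adaptor (243 ± 165 against 0.813 ± 0.810), the complement gene C1qc (65.0 ± 35.1 against 0.154 ± 0.165) and S100a9, a calcium-binding protein of neutrophils (384 ± 223 against 2.06 ± 1.55). Cell cycle genes were higher for 22 of 26 (24 adjusted over the list alone, 20 kept, median 0.87, camera adjusted p = 2.83e-05, or 0.434 by estimated correlation), such as the ribonucleotide reductase subunit Rrm2 (86.6 ± 69.0 against 38.1 ± 30.7). The list mean was 5.01 and 5.30 in immune against 5.24 and 5.28 in endothelial libraries at E16.5, 3.92 and 3.60 against 4.16 and 4.03 at P7, and 5.37 and 3.62 against 3.03 and 2.70 at P28. The pore-forming protein gene Mpeg1 (6.80 ± 0.31), Ccl6 (6.59 ± 0.29), Mcemp1 (6.41 ± 0.25), the cathepsin Ctss (6.32 ± 0.25) and Ifitm6 (6.26 ± 0.27) differed most outside the lists. Adamts1 (-3.27 ± 0.22), Adgrf5 (-3.16 ± 0.18), Crip2 (-2.88 ± 0.16), Mageh1 (-2.84 ± 0.27) and the small heat shock protein Hspb1 (-2.80 ± 0.22) were lowest. Epcam, 14.0 ± 17.5 against 25.7 ± 28.9, did not pass as deposited (-0.57 ± 0.25, limma adjusted p = 0.0695) and passed after rescaling (-0.61, limma adjusted p = 0.0472) or with a block by pool (limma adjusted p = 0.0488 fixed, 0.0432 random). It also passed without endothelial E16.5 replicate 2, immune E16.5 replicate 1, endothelial P28 replicate 1 or endothelial P7 replicate 1 (limma adjusted p = 0.00686 at the lowest). Limma called 3295 genes higher and 3844 lower.

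Each fraction also held transcripts of the others, in amounts that changed with age. The 14 epithelial identity genes stood, as a median, at 7.38% and 0.68% of their epithelial level in the E16.5 endothelial libraries. The share was 29.26% and 41.47% at E18.5, 4.75% and 11.87% at P7, and 12.29% and 24.24% at P28. In the immune libraries it was 49.63% and 32.34% at E16.5, 20.45% and 12.27% at P7, and 1.20% and 3.09% at P28. Endothelial identity genes stood at 9.38% and 8.05% of their endothelial level in the P7 epithelial libraries and at 0.77% and 0.48% at P28, and at 12.46% and 6.54% in the P7 immune libraries and 0.12% and 0.39% at P28. A change of such genes in a fraction not sorted for them moved together with these shares.

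**Figure D1:**
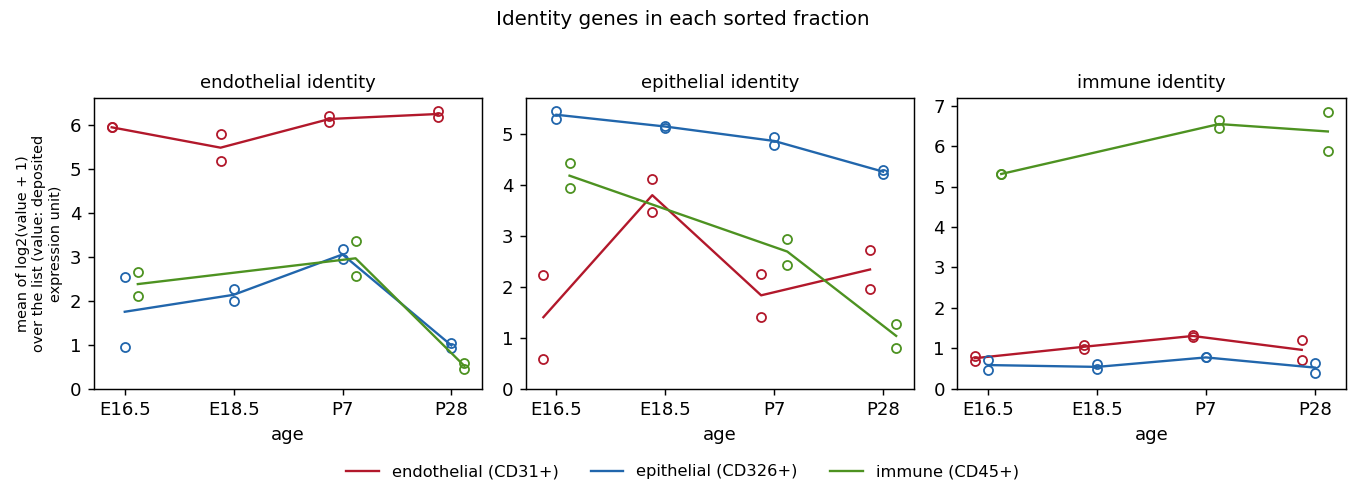
Each panel plots, against age, the mean of log2(value + 1) over the genes of an identity list, in the deposited signal unit; circles are libraries, lines join group means and colours mark the sorted fraction, with no immune library at E18.5. The fraction sorted for a list lay highest in its panel at every age, and the epithelial list showed the endothelial libraries at E18.5 and the immune libraries at E16.5 nearest to the epithelial ones.

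In endothelial cells, the comparison of P28 with E16.5 spanned development from the embryonic to the juvenile lung. Car4-type capillary, antigen presentation and interferon genes rose, and imprinted and oncofetal growth genes (growth genes) and cell cycle genes fell. Of 8 genes of the Car4 type of capillary cell, 7 rose (7 adjusted over the list alone, 6 kept, median log2 fold change 2.23, camera adjusted p = 1.42e-06, or 0.168 by estimated correlation). Car4, a membrane-bound carbonic anhydrase (chromosome 11, 84957786 to 84966044), went from 0.521 ± 0.487 to 120 ± 6.57 (log2 fold change 6.35 ± 0.50, limma adjusted p = 4.66e-07). Of 8 general capillary genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone, 2 and 1 kept, median 0.75, camera adjusted p = 0.147, or 0.729 by estimated correlation). Of 6 venous genes, 4 rose (4 adjusted over the list alone, 4 kept, median 1.57, camera adjusted p = 0.00109, or 0.168 by estimated correlation), including Slc6a2, the noradrenaline transporter (0.0734 ± 0.0629 to 62.2 ± 14.4), and Vwf, von Willebrand factor (6.69 ± 0.714 to 49.3 ± 3.36).

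All 10 MHC class I genes rose (10 adjusted over the list alone, 10 kept, median 2.76, camera adjusted p = 1.20e-11, or 0.0126 by estimated correlation). H2-K1 (chromosome 17, 33996017 to 34000347), a class I heavy chain, went from 18.5 ± 2.73 to 877 ± 47.2 (log2 fold change 5.50 ± 0.31, limma adjusted p = 2.51e-08). Of 9 MHC class II and dendritic cell genes, 7 rose (7 adjusted over the list alone, 6 kept, median 2.00, camera adjusted p = 1.68e-05, or 0.252 by estimated correlation). The class II invariant chain Cd74 went from 0.652 ± 0.538 to 87.2 ± 6.24, and H2-Aa from 0.126 ± 0.0137 to 57.4 ± 7.46; in P28 epithelial libraries they stood at 483 ± 51.1 and 207 ± 2.12. Ptprc, the marker of the immune fraction, stayed at 0.195 ± 0.0928 at P28 (log2 fold change 0.19 ± 0.25, limma adjusted p = 0.633). Of 12 interferon response genes, 10 rose (11 adjusted over the list alone, 8 kept, median 1.40, camera adjusted p = 1.40e-07, or 0.0415 by estimated correlation), led by Ifit3, an inhibitor of viral translation (0.166 ± 0.146 to 20.3 ± 0.0229).

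All 13 growth genes fell (13 adjusted over the list alone, 10 kept, median -2.55, camera adjusted p = 1.20e-11, or 0.0026 by estimated correlation). The noncoding RNA H19 fell from 1040 ± 105 to 13.9 ± 0.194, Mest from 2030 ± 142 to 41.8 ± 7.29 and the growth factor gene Igf2 from 358 ± 14.2 to 13 ± 0.328 (log2 fold change -4.68 ± 0.42, limma adjusted p = 1.99e-06). Cell cycle genes fell for 25 of 26 (26 adjusted over the list alone, 24 kept, median -2.42, camera adjusted p = 4.33e-15, or 0.252 by estimated correlation), such as cyclin B1, Ccnb1 (70.4 ± 4.42 to 6.74 ± 0.0933). Of 12 immediate early and dissociation genes, 6 rose (12 adjusted over the list alone, 1 kept, median 2.08, camera adjusted p = 1.26e-04, or 0.339 by estimated correlation). Among these, the phosphatase Dusp1 went from 144 ± 46.9 to 871 ± 49.3, while the heat shock gene Hspa1a (2.88 ± 0.68, limma adjusted p = 0.0057) lost its call without endothelial E16.5 replicate 2 (limma adjusted p = 0.0781).

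The largest rises outside the lists were Ccl21c, a chemokine gene copy (7.72 ± 1.6), complement C3 (6.14 ± 0.58), Fmo1 (5.76 ± 0.26) and Tgtp2 (5.57 ± 0.38). Chil1, a chitinase-like protein gene, was listed at 0 at E16.5 and at 100 ± 42.7 at P28 (limma adjusted p = 5.21e-07). The largest falls were the histone Hist1h2bk (-5.46 ± 1.1), Hif3a, a hypoxia-inducible factor subunit (-5.32 ± 0.32), Prnd (-4.57 ± 0.71) and the lysophosphatidic acid receptor Lpar4 (-4.31 ± 0.30); the embryonic globin Hba-x went from 25.8 ± 17.1 to a listed 0. Without endothelial P28 replicate 2, Hist1h2bk lost its call (limma adjusted p = 0.0516). Limma called 3583 genes, 1752 higher and 1831 lower, and 2067 and 1468 after rescaling. Leave-one-out fits called 1976 to 2456. Pecam1 was not called (80.6 ± 7.79 against 74.0 ± 2.49, log2 fold change 0.12 ± 0.46, limma adjusted p = 0.899).

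Epithelial transcripts rose in P28 endothelial libraries too, and C3, Chil1 and class II genes were not tested apart from them. All 13 alveolar type 2 genes were higher than at E16.5 (13 adjusted over the list alone, 10 kept, median 4.79, camera adjusted p = 1.37e-10, or 0.221 by estimated correlation), such as the lysozyme Lyz2 (6.53 ± 1.70 to 2380 ± 746) and Sftpc (204 ± 257 to 5110 ± 1470). Of 12 alveolar type 1 genes, 9 were higher (10 adjusted over the list alone, 8 kept, median 2.58, camera adjusted p = 3.70e-08, or 0.221 by estimated correlation), among them the water channel Aqp5 (0.231 ± 0.327 to 32.2 ± 22.2) and Ager (12.9 ± 13.9 to 195 ± 120). Of 14 epithelial identity genes, only Cldn18 passed (8.46 ± 10.4 to 34.6 ± 20.9, limma adjusted p = 0.0243; none adjusted over the list alone, none kept, median 1.06, camera adjusted p = 0.0238, or 0.0527 rescaled, or 0.696 by estimated correlation). Without endothelial E16.5 replicate 2, Cldn18 lost its call (limma adjusted p = 0.378), and without replicate 1 of that group Epcam gained one (limma adjusted p = 0.0277, against 0.342 with all libraries).

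From E16.5 to E18.5, epithelial and some glycolysis and hypoxia genes rose in endothelial libraries. All 13 alveolar type 2 genes rose (13 adjusted over the list alone, 10 kept, median 4.10, camera adjusted p = 9.00e-17, or 0.160 by estimated correlation). All 14 epithelial identity genes rose as well (14 adjusted over the list alone, 1 kept, median 2.40, camera adjusted p = 1.80e-12, or 0.242 by estimated correlation). Lyz1 went from 1.22 ± 1.63 to 301 ± 142 (log2 fold change 7.23 ± 0.58, limma adjusted p = 5.84e-06) and the keratin Krt18 from 2.62 ± 3.58 to 31.7 ± 14.7. Epcam rose by 2.22 ± 0.51 (limma adjusted p = 0.0118) but lost its call without endothelial E16.5 replicate 2 (limma adjusted p = 0.189). Of 12 glycolysis and hypoxia genes, 3 rose (6 adjusted over the list alone, 2 kept, median 0.53, camera adjusted p = 0.00121, or 0.160 by estimated correlation), including the vascular growth factor Vegfa (7.67 ± 2.98 to 80.0 ± 12.5) and the mitophagy receptor Bnip3 (1.89 ± 0.106 to 8.56 ± 1.92). Cell cycle genes fell for 2 of 26 (8 adjusted over the list alone, none kept, median -1.04, camera adjusted p = 3.74e-06, or 0.746 by estimated correlation): Mcm4 (39.5 ± 3.18 to 13.7 ± 4.93) and Bub1 (15.2 ± 2.20 to 5.18 ± 0.499). Mcm4 lost its call without endothelial E18.5 replicate 2 (limma adjusted p = 0.161) and Bub1 without endothelial E16.5 replicate 2 (limma adjusted p = 0.226) or after rescaling (limma adjusted p = 0.0664).

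Outside the lists, Chil1 was listed at 0 at E16.5 and was higher at E18.5 (limma adjusted p = 5.54e-06), and Retnla, a resistin-like cytokine gene, rose by 4.73 ± 0.65 on the log2 scale. Clic3 (4.53 ± 0.83), Sfta2 (4.37 ± 0.76) and Muc1 (4.29 ± 0.76), which marked the epithelial fraction, followed. The falls were Hba-x (-4.16 ± 0.76), the early response gene Egr3 (-2.52 ± 0.57), Myc (-2.22 ± 0.43), Peg10 (-2.15 ± 0.33) and Hlx (-1.77 ± 0.37). Limma called 887 genes higher and 617 lower, and 922 and 398 after rescaling; without the genes of the epithelial fraction it called 312 higher and 427 lower. The count of 1504 was 249 without both libraries described with another age, 697 without endothelial E16.5 replicate 1, 314 without replicate 2 of that group and 609 without endothelial E18.5 replicate 2. The last of these fits ended the call of Egr3 (limma adjusted p = 0.13), and leaving out endothelial E16.5 replicate 2 ended those of Myc (limma adjusted p = 0.0682) and Hlx (limma adjusted p = 0.0731).

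Between E18.5 and P7, across birth, glycolysis and hypoxia genes fell in endothelial cells and antigen presentation genes rose. Of 12 glycolysis and hypoxia genes, 10 fell (11 adjusted over the list alone, 3 kept, median -1.20, camera adjusted p = 4.72e-12, or 0.00291 by estimated correlation). The oxygen sensor Egln3 fell from 14.5 ± 1.04 to 0.992 ± 0.234 (log2 fold change -2.97 ± 0.34, limma adjusted p = 6.66e-05) and the glucose transporter Slc2a1 from 13.3 ± 1.35 to 2.41 ± 0.393. Hif3a (chromosome 7, 17031507 to 17062427) fell from 109 ± 18.6 to 1.22 ± 0.750 (-5.67 ± 0.32, limma adjusted p = 1.39e-07). Of 10 MHC class I genes, 8 rose (9 adjusted over the list alone, 5 kept, median 1.84, camera adjusted p = 4.64e-10, or 0.0155 by estimated correlation). H2-K1 went from 61.0 ± 0.540 to 409 ± 143. Of 6 venous genes, 4 rose (5 adjusted over the list alone, 2 kept, median 0.97, camera adjusted p = 5.95e-06, or 0.0392 by estimated correlation), led by Slc6a2 (0.549 ± 0.191 to 38.7 ± 18.1).

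Growth genes split at this step: 4 of 13 fell (6 adjusted over the list alone, 3 kept, median -1.04, camera adjusted p = 1.32e-06, or 0.0155 by estimated correlation), among them Dlk1 (67.9 ± 33.0 to 2.64 ± 2.23) and Meg3 (63.4 ± 3.54 to 3.84 ± 1.74), which with Rtl1 lie in a cluster on chromosome 12 (Dlk1 from 109452823 to 109463336). Peg3 rose (1.94 ± 0.53, limma adjusted p = 0.032) but lost its call without endothelial P7 replicate 2 (limma adjusted p = 0.39). Of 14 epithelial identity genes, 10 fell (13 adjusted over the list alone, 1 kept, median -2.11, camera adjusted p = 4.72e-12, or 0.209 by estimated correlation), and Epcam fell from 13.4 ± 3.96 to 2.12 ± 1.5, though not without endothelial E18.5 replicate 2 (limma adjusted p = 0.108). The other large rises were Tgtp2 (4.57 ± 0.38), the prostaglandin-degrading enzyme Hpgd (4.37 ± 0.50), H2-Q5 (3.77 ± 0.71), Tmem100 (3.74 ± 0.36) and Fmo1 (3.21 ± 0.26). Retnla (-5.10 ± 0.65), the glycogen-targeting phosphatase subunit Ppp1r3b (-4.13 ± 0.44), Bex1 (-3.53 ± 0.53) and Rtl1 (-3.41 ± 0.28) fell most after Hif3a. H2-Q5 lost its call without endothelial P7 replicate 2 (limma adjusted p = 0.0546). Limma called 1265 genes, 742 higher and 523 lower; leave-one-out fits called 583 to 1075.

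From P7 to P28 endothelial growth genes and some cell cycle genes fell. Of 13 growth genes, 9 fell (10 adjusted over the list alone, 4 kept, median -1.34, camera adjusted p = 6.78e-11, or 0.00322 by estimated correlation). Igf2 went from 312 ± 230 to 13 ± 0.328 (log2 fold change -4.26 ± 0.42, limma adjusted p = 5.41e-05). Of 26 cell cycle genes, 6 fell (17 adjusted over the list alone, none kept, median -1.29, camera adjusted p = 6.78e-11, or 0.398 by estimated correlation), such as the mitotic kinase Aurkb (30.2 ± 3.55 to 7.11 ± 2.15), which lost its call without endothelial P28 replicate 2 (limma adjusted p = 0.141), and Ccnb2, Cenpe and Foxm1, which lost theirs without any 1 of the 4 libraries (limma adjusted p up to 0.21, 0.222 and 0.309). Of 8 Car4-type capillary genes, 2 rose (4 adjusted over the list alone, none kept, median 0.82, camera adjusted p = 5.40e-05, or 0.292 by estimated correlation): Fibin (23.6 ± 1.03 to 126 ± 13.5) and Chst1 (2.36 ± 0.129 to 4.90 ± 0.302). Both lost their call without endothelial P28 replicate 1 (limma adjusted p = 0.195 and 0.0651). Of 12 interferon response genes, 3 rose (4 adjusted over the list alone, none kept, median 0.77, camera adjusted p = 1.11e-06, or 0.0957 by estimated correlation). Ifit3 went from 5.19 ± 4.03 to 20.3 ± 0.0229, but lost its call without endothelial P7 replicate 1 (limma adjusted p = 0.122), as did Oas1a and Usp18 without endothelial P28 replicate 1 (limma adjusted p = 0.0854 and 0.143).

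The methyltransferase Inmt (4.71 ± 0.49), the aryl hydrocarbon receptor target Cyp1a1 (4.26 ± 0.19), Ankrd63 (3.00 ± 0.30), Ccdc184 (2.90 ± 0.38) and haptoglobin, Hp (2.81 ± 0.48), rose most in this step. The histone Hist1h3f (-3.44 ± 0.59), Ctxn1 (-2.60 ± 0.38), the matrix protein Fbln2 (-2.59 ± 0.37), Mex3a (-2.58 ± 0.64) and Nrep (-2.53 ± 0.35) fell most. Calls were lost for Hist1h3f without endothelial P28 replicate 1 (limma adjusted p = 0.0613), for Hp without replicate 2 of that group (limma adjusted p = 0.0514) and for Mex3a without endothelial P7 replicate 2 (limma adjusted p = 0.197) or after rescaling (limma adjusted p = 0.0573). Limma called 234 genes higher and 320 lower, and 315 and 228 after rescaling. Leave-one-out fits called 166 to 264 genes, against 554.

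In epithelial cells, P28 differed from E16.5 by a secretory and surfactant program that rose and an embryonic program that fell. Of 13 alveolar type 2 genes, 10 rose (10 adjusted over the list alone, 6 kept, median log2 fold change 2.78, rescaled 3.83, camera adjusted p = 3.21e-13, or 0.142 by estimated correlation). Lyz2, a lysozyme, went from 14.7 ± 0.103 to 12500 ± 3470 (log2 fold change 9.60 ± 0.53, rescaled 10.6, limma adjusted p = 1.55e-08) and the surfactant collectin Sftpd from 1.77 ± 0.343 to 256 ± 2.71 (6.54 ± 0.51, rescaled 7.47). Of 8 club and secretory genes, 7 rose (7 adjusted over the list alone, 7 kept, median 3.61, rescaled 4.59, camera adjusted p = 4.90e-13, or 0.0737 by estimated correlation), led by Scgb1a1, the club cell secretoglobin (chromosome 19, 9083636 to 9087958), from 30.5 ± 0.525 to 20700 ± 5700 (9.33 ± 0.83, rescaled 10.4). Of 9 ciliated genes, 5 rose (5 adjusted over the list alone, 3 kept, median 0.69, rescaled 1.59, camera adjusted p = 7.29e-06, or 0.151 by estimated correlation), such as Tppp3 (17.7 ± 2.18 to 86.0 ± 14.7). Dynlrb2, a dynein light chain of the ciliated list, lost its call without epithelial P28 replicate 1 (limma adjusted p = 0.0796).

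Some lipid and redox genes rose as well. Of 14 surfactant lipid synthesis genes, 5 rose and 1 fell (5 and 1 adjusted over the list alone, 3 and 0 kept, median 0.35, rescaled 1.3, camera adjusted p = 2.32e-05, or 0.223 by estimated correlation). The desaturase Scd1 went from 38.5 ± 14.1 to 2750 ± 697 (6.15 ± 0.73, rescaled 7.20), while the fatty acid synthase Fasn (1.09 ± 0.36, rescaled 2.14) lost its call without epithelial P28 replicate 2 (limma adjusted p = 0.143). Of 11 antioxidant genes, 6 rose and 1 fell (6 and 1 adjusted over the list alone, 4 and 0 kept, median 0.82, rescaled 1.85, camera adjusted p = 4.03e-06, or 0.151 by estimated correlation). The peroxiredoxin Prdx6 went from 19.6 ± 0.579 to 104 ± 43.7. Of 12 alveolar type 1 genes, the water channel Aqp5 rose (2.14 ± 0.532 to 69.5 ± 25.5), and Akap5 and Cav1 fell (-1.91 ± 0.74 and -1.19 ± 0.43, rescaled -0.85 and -0.19). The median of that list was -0.25, its mean 0.15 and its rescaled median 0.73; camera placed it higher (camera adjusted p = 0.022, or 0.572 by estimated correlation), and 1 gene was higher adjusted over the list alone. Akap5 lost its call without epithelial P28 replicate 1 (limma adjusted p = 0.139) and Cav1 without epithelial E16.5 replicate 1 (limma adjusted p = 0.291).

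Antigen presentation rose in the epithelium as well. Of 10 MHC class I genes, 7 rose (7 adjusted over the list alone, 4 kept, median 0.97, rescaled 1.75, camera adjusted p = 1.53e-09, or 0.0296 by estimated correlation). H2-D1 went from 26.9 ± 3.38 to 201 ± 9.30 (2.86 ± 0.35, rescaled 3.90). Of 9 class II genes, 7 rose (7 adjusted over the list alone, 6 kept, median 2.57, rescaled 3.37, camera adjusted p = 3.13e-10, or 0.103 by estimated correlation). H2-Aa went from 2.93 ± 3.96 to 207 ± 2.12. Ptprc stayed at 0.0383 ± 0.0296 (limma adjusted p = 0.963). Of 12 interferon response genes, 4 rose (4 adjusted over the list alone, 1 kept, median 0.42, rescaled 1.04, camera adjusted p = 5.82e-06, or 0.0737 by estimated correlation), led by Ifit3 (2.02 ± 0.40, rescaled 2.67). Without epithelial P28 replicate 1, calls of Ifit1, Irf7 and Isg15 were lost (limma adjusted p = 0.194, 0.171 and 0.0713).

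Progenitor and growth genes fell. All 13 growth genes were lower (13 adjusted over the list alone, 12 kept, median -4.30, rescaled -3.40, camera adjusted p = 1.68e-08, or 0.0115 by estimated correlation): H19 fell from 4460 ± 301 to 0.497 ± 0.562 (-11.6 ± 0.97, rescaled -11.0) and Igf2 (chromosome 7, 142650766 to 142666816) from 1130 ± 104 to 2.15 ± 0.925 (-8.52 ± 0.42, rescaled -7.67). Of 6 distal tip progenitor genes, 5 fell (5 adjusted over the list alone, 5 kept, median -2.72, rescaled -2.28, camera adjusted p = 0.00407, or 0.210 by estimated correlation), including the tip transcription factor Sox9 (95.0 ± 16.5 to 0.750 ± 0.363). Of 26 cell cycle genes, 25 fell (26 adjusted over the list alone, 25 kept, median -2.57, rescaled -1.76, camera adjusted p = 5.82e-06, or 0.563 by estimated correlation). The proliferation marker Mki67 went from 267 ± 9.49 to 21.6 ± 13.7.

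Outside the lists, Chil1 (7.97 ± 0.53, rescaled 8.88), the siderophore-binding protein gene Lcn2 (6.73 ± 0.60, rescaled 7.67) and S100g (5.41 ± 0.50, rescaled 6.39) rose most, with Lrg1 and the cytochrome oxidase subunit Cox6a2, which were listed at 0 at E16.5 and at 86.8 ± 52.5 and 48.7 ± 4.70 at P28. The claudin Cldn6 (-8.16 ± 0.66, rescaled -7.50), Hif3a (-6.42 ± 0.32, rescaled -5.78), fibromodulin, Fmod (-6.32 ± 0.45, rescaled -5.69), the growth factor Mdk (-5.93 ± 0.44, rescaled -5.25) and Nt5dc2 (-5.30 ± 0.71, rescaled -4.49) fell most. As deposited, limma called 705 genes higher and 6395 lower; after rescaling it called 2396 higher and 1943 lower. Epcam fell as deposited (78.9 ± 11.2 to 30.1 ± 6.27, -1.37 ± 0.51, limma adjusted p = 0.0327) but not after rescaling (-0.34, limma adjusted p = 0.668) or without epithelial P28 replicate 2 (limma adjusted p = 0.156). Pecam1 was not called (-1.10 ± 0.46, limma adjusted p = 0.0519) but passed without epithelial E16.5 replicate 2 (limma adjusted p = 0.00128) or with a block by pool (limma adjusted p = 0.0447).

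The first epithelial step, from E16.5 to E18.5, raised some of the alveolar genes. Of 13 alveolar type 2 genes, 4 rose (7 adjusted over the list alone, 3 kept, median 1.84, rescaled 2.16, camera adjusted p = 4.6e-10, or 0.279 by estimated correlation), with Lyz1 from 19 ± 4.93 to 913 ± 86.8 (5.53 ± 0.58, rescaled 5.83, limma adjusted p = 1.04e-04). Of 12 alveolar type 1 genes, 5 rose and 1 fell (7 and 1 adjusted over the list alone, 2 and 0 kept, median 1.11, rescaled 1.41, camera adjusted p = 1.23e-07, or 0.279 by estimated correlation). Of 14 surfactant lipid genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone, 1 and 0 kept, median 0.61, rescaled 0.90, camera adjusted p = 1.59e-05, or 0.279 by estimated correlation), such as Scd1 (38.5 ± 14.1 to 698 ± 55.8). The cell cycle fell for 25 of 26 genes, and 13 after rescaling (26 adjusted over the list alone, 6 kept, median -1.94, rescaled -1.65, camera adjusted p = 3.43e-13, or 0.318 by estimated correlation). Aurkb went from 36.0 ± 0.981 to 6.58 ± 1.57. Of 6 distal tip genes, 3 fell (5 adjusted over the list alone, 2 kept, median -1.08, rescaled -0.81, camera adjusted p = 0.00903, or 0.279 by estimated correlation), among them Sox11 (57 ± 0.178 to 14.3 ± 1.26).

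Chil1 (7.02 ± 0.53, rescaled 7.19), Lcn2 (5.18 ± 0.60, rescaled 5.38), C3 (4.06 ± 0.58, rescaled 4.22), Gdpd2 (3.68 ± 0.44, rescaled 3.87) and the pantetheinase Vnn1 (3.37 ± 0.38, rescaled 3.61) rose most. Mdk (-3.17 ± 0.44, rescaled -2.86) and the proteoglycan Vcan (-2.86 ± 0.34, rescaled -2.56) fell with the histones Hist1h2ag (-3.26 ± 0.78, rescaled -2.96), Hist1h2bh (-3.17 ± 0.66, rescaled -2.86) and Hist3h2ba (-2.82 ± 0.90, rescaled -2.54). The histone calls were lost without epithelial E18.5 replicate 1 (Hist1h2ag, limma adjusted p = 0.155), E18.5 replicate 2 (Hist1h2bh, limma adjusted p = 0.0706) and E16.5 replicate 1 (Hist3h2ba, limma adjusted p = 0.221, or 0.106 rescaled). Limma called 371 genes higher and 1344 lower, and 602 and 456 after rescaling. Leave-one-out fits called 409 to 667 genes, against 1715.

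Across birth, from E18.5 to P7, club cell and class II genes rose in the epithelium and glycolysis and hypoxia genes fell. Of 8 club and secretory genes, 4 rose (7 adjusted over the list alone, 3 kept, median 2.43, camera adjusted p = 2.06e-09, or 0.129 by estimated correlation). Scgb1a1 went from 164 ± 8.48 to 11200 ± 3520 (log2 fold change 6.05 ± 0.83, limma adjusted p = 5.26e-04). Of 9 class II genes, 4 rose (7 adjusted over the list alone, 4 kept, median 1.44, camera adjusted p = 2.06e-09, or 0.129 by estimated correlation). Cd74 went from 28.5 ± 3.17 to 386 ± 123. Of 12 glycolysis and hypoxia genes, 9 fell (10 adjusted over the list alone, 3 kept, median -1.18, camera adjusted p = 3.81e-10, or 0.00542 by estimated correlation). Egln3 went from 9.84 ± 0.386 to 0.173 ± 0.0119. Of 13 growth genes, 7 fell (9 adjusted over the list alone, 4 kept, median -0.92, camera adjusted p = 2.03e-07, or 0.00964 by estimated correlation). Dlk1 went from 221 ± 2.98 to 20.7 ± 5.21.

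BC021614 (3.34 ± 0.56), Tmem100 (3.14 ± 0.36), the zinc transporter Slc39a2 (3.14 ± 0.69), the cold-inducible RNA-binding protein Cirbp (3.02 ± 0.34) and the olfactory receptor Olfr1342 (3.00 ± 0.65) rose most over this step. The falls were Hif3a (166 ± 9.85 to 3.26 ± 1.97, -5.38 ± 0.32), Ppp1r3b (-4.55 ± 0.44), Rtl1 (-3.82 ± 0.28), Tmem213 (-3.66 ± 0.30) and Nt5dc2 (-3.51 ± 0.71). Calls ended for Slc39a2 and Olfr1342 without epithelial E18.5 replicate 1 (limma adjusted p = 0.159 and 0.187), for BC021614 without replicate 2 of that group (limma adjusted p = 0.0533) and for Nt5dc2 without epithelial P7 replicate 2 (limma adjusted p = 0.0780). Limma called 288 genes higher and 322 lower; after rescaling, 293 of 799 called genes were lower. Leave-one-out fits called 197 to 396 genes, against 610.

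From P7 to P28, epithelial libraries lost growth, basement membrane and endothelial transcripts. Of 13 growth genes, 12 fell (12 adjusted over the list alone, 8 kept, median -1.83, rescaled -1.47, camera adjusted p = 8.61e-10, or 0.00455 by estimated correlation). H19 went from 66.9 ± 39.7 to 0.497 ± 0.562. Of 12 basement membrane genes, 11 fell (12 adjusted over the list alone, 8 kept, median -1.58, rescaled -1.23, camera adjusted p = 5.82e-08, or 0.274 by estimated correlation), such as the laminin Lamc1 (21.8 ± 4.32 to 4.04 ± 0.551). Beside them, 12 of 14 endothelial identity genes fell (13 adjusted over the list alone, 7 kept, median -2.17, rescaled -1.96, camera adjusted p = 8.75e-07, or 0.298 by estimated correlation). Cdh5 went from 24.4 ± 0.694 to 1.42 ± 0.261. Of 12 alveolar type 1 genes, 8 fell as deposited and 3 after rescaling (9 adjusted over the list alone, 3 kept, median -1.45, rescaled -0.86, camera adjusted p = 6.30e-04, or 0.368 by estimated correlation). Sprr1a, a cornified envelope protein gene (3.13 ± 0.32, rescaled 3.78), Cox6a2 (2.97 ± 0.36, rescaled 3.58), Hes2 (2.08 ± 0.45, rescaled 2.68), Itih4 (2.07 ± 0.40, rescaled 2.69) and the prostaglandin synthase Ptgs2 (1.90 ± 0.28, rescaled 2.50) rose. The vascular genes Sox18 (-4.38 ± 0.50, rescaled -4.03), Lyve1 (-4.19 ± 0.68, rescaled -3.92), Mcam (-3.78 ± 0.50, rescaled -3.42), Sox7 (-3.75 ± 0.56, rescaled -3.53) and Aqp1 (-3.59 ± 0.34, rescaled -3.06) fell most.

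Scaling and library choice changed the count at this step. Limma called 119 genes higher and 2623 lower, and 479 and 641 after rescaling. The total of 2742 was 589 and 1670 without epithelial P28 replicates 1 and 2, and 579 without epithelial P7 replicate 2, the library of another sequencing run. Within the shared run, 8 of 13 growth genes, 8 of 12 basement membrane genes, 8 of 14 endothelial identity genes and 4 of 12 alveolar type 1 genes were still called lower. Without epithelial P7 replicate 2, Pecam1 (-2.19 ± 0.46, rescaled -2.04, limma adjusted p = 0.00547) lost its call (limma adjusted p = 0.0511), as did Akap5 and Cav1 (limma adjusted p = 0.126 for both), and Hes2 lost its call without epithelial P28 replicate 2 (limma adjusted p = 0.0599).

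In immune cells, P28 differed from E16.5 by a gain of lymphocyte, alveolar macrophage and antigen presentation genes. Of 7 natural killer cell genes, 7 rose (7 adjusted over the list alone, 6 kept, median log2 fold change 2.15, rescaled 2.51, camera adjusted p = 1.26e-11, or 0.0354 by estimated correlation), such as the chemokine Ccl5 (0.645 ± 0.457 to 41.8 ± 41.6, 4.27 ± 0.47, rescaled 4.57, limma adjusted p = 1.24e-05). All 6 B cell genes rose (6 adjusted over the list alone, 5 kept, median 2.98, rescaled 3.21, camera adjusted p = 1.5e-10, or 0.0504 by estimated correlation). Cd79a, a B cell receptor chain, went from 1.07 ± 0.230 to 23.7 ± 18.8. Of 9 alveolar macrophage genes, 6 rose (6 adjusted over the list alone, 6 kept, median 3.73, rescaled 4.05, camera adjusted p = 1.5e-10, or 0.0504 by estimated correlation). The chitinase-like Chil3 went from 2.09 ± 1.23 to 786 ± 753. Class II genes rose for 8 of 9 (8 adjusted over the list alone, 6 kept, median 2.52, rescaled 2.96, camera adjusted p = 1.26e-11, or 0.0504 by estimated correlation). Of 12 immune identity genes, 8 rose (9 adjusted over the list alone, 2 kept, median 1.05, rescaled 1.49, camera adjusted p = 1.06e-08, or 0.0504 by estimated correlation). Ptprc went from 10.5 ± 4.98 to 43.7 ± 16.4. Among immune identity genes, Cd52 lost its call without immune E16.5 replicate 2 (limma adjusted p = 0.141) and Tyrobp without immune P28 replicate 2 (limma adjusted p = 0.453).

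Antigen presentation genes rose and growth genes fell. All 10 MHC class I genes rose (10 adjusted over the list alone, 7 kept, median 1.62, rescaled 2.00, camera adjusted p = 1.15e-13, or 0.00609 by estimated correlation). B2m went from 401 ± 56.1 to 1320 ± 564. Of 12 interferon response genes, 7 rose (7 adjusted over the list alone, 4 kept, median 1.01, rescaled 1.42, camera adjusted p = 4.24e-08, or 0.0354 by estimated correlation). Irf7 went from 3.54 ± 0.476 to 14.5 ± 3.04. All 13 growth genes fell (13 adjusted over the list alone, 13 kept, median -4.96, rescaled -4.73, camera adjusted p = 1.26e-13, or 0.00119 by estimated correlation). Igf2 went from 407 ± 99.0 to 0.164 ± 0.0733. Of 26 cell cycle genes, 2 fell (none adjusted over the list alone, none kept, median -0.73, rescaled -0.30, camera adjusted p = 0.529, or 0.94 by estimated correlation): Ccnb1 and Bub1, which both lost their call without immune P28 replicate 2 (limma adjusted p = 0.508 and 0.295) or after rescaling (0.186 and 0.132). Of 14 epithelial identity genes, 13 fell (13 adjusted over the list alone, 13 kept, median -3.23, rescaled -2.94, camera adjusted p = 9.52e-08, or 0.249 by estimated correlation). Nkx2-1 went from 179 ± 30.5 to 1.83 ± 1.81 and Epcam from 35.2 ± 13.5 to 2.06 ± 0.432.

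T cell genes rested on single libraries. Of 10 genes, 5 were higher at P28 (8 adjusted over the list alone, none kept, median 2.38, rescaled 2.73, camera adjusted p = 1.19e-06, or 0.258 by estimated correlation). Cd8a went from 34.0 ± 47.2 to 247 ± 297, and Thy1 from 67.5 ± 91.1 to 308 ± 332. Without immune E16.5 replicate 1, the calls of Cd8a, Thy1, Cd3d and Cd4 ended (limma adjusted p = 0.498, 0.611, 0.506 and 0.111). The median log2 difference of the T cell list between replicates was 4.08 at E16.5 (replicate 2 higher) and 2.56 at P28 (replicate 1 higher). For 18 immature thymocyte genes, none of them in the T cell list, it was 2.15 and 3.41, against 0.61 and -0.56 for 15 mature T cell genes. Rag1, which cuts antigen receptor genes in the thymus, was at 210 against 1.37 and at 430 against 0.727.

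**Figure D2:**
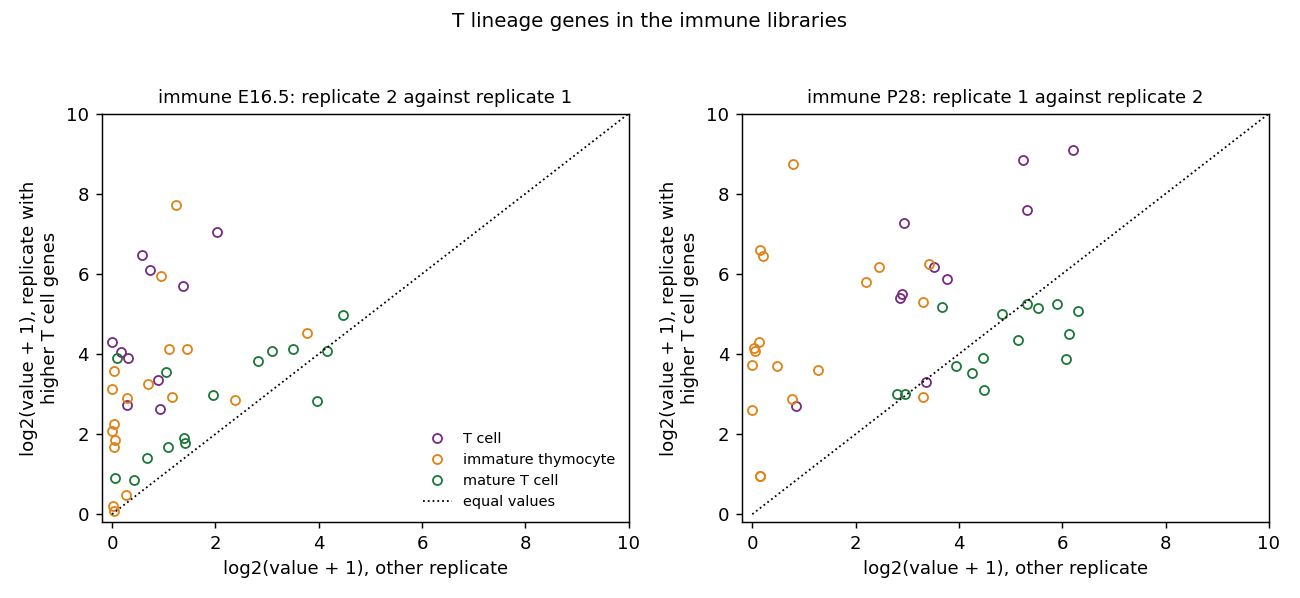
Each panel plots log2(value + 1) in the immune replicate with higher T cell genes (y axis) against the other replicate (x axis), at E16.5 and at P28; points are genes of 3 lists and the dotted line marks equal values. Most immature thymocyte genes lay above the line.

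Outside the lists, the fatty acid binding protein Fabp1 (5.07 ± 0.56, rescaled 5.29), the vacuolar ATPase subunit Atp6v0d2 (4.66 ± 0.45, rescaled 4.90), Il1b (4.6 ± 0.38, rescaled 4.89), Ly6d (4.59 ± 0.58, rescaled 4.90) and the GTPase Gimap3 (4.30 ± 0.30, rescaled 4.66) rose most. Cldn6 (-7.55 ± 0.66, rescaled -7.31), Prrg3 (-5.66 ± 0.37, rescaled -5.26), Fmod (-5.40 ± 0.45, rescaled -5.14), Hif3a (-5.39 ± 0.32, rescaled -5.09) fell most, with the imprinted gene Nnat. Limma called 630 genes higher and 3271 lower, and 1295 and 1766 after rescaling; leave-one-out fits called 2523 to 4574 genes, against 3901. Rsad2 lost its interferon call without immune P28 replicate 2 (limma adjusted p = 0.0775), and Pecam1 (-1.03 ± 0.46, limma adjusted p = 0.1) passed without immune E16.5 replicate 1 (limma adjusted p = 0.0481).

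From E16.5 to P7, alveolar macrophage and B cell genes rose in the immune fraction. The lists that passed with an estimated correlation were growth genes (11 of 13 fell, 11 adjusted over the list alone, 8 kept, median -1.84, rescaled -1.58, camera adjusted p = 7.03e-09, or 0.00711 by estimated correlation) and MHC class I (7 of 10 rose, 8 adjusted over the list alone, 6 kept, median 1.56, rescaled 1.80, camera adjusted p = 7.30e-09, or 0.0368 by estimated correlation). Of 9 alveolar macrophage genes, 6 rose (7 adjusted over the list alone, 6 kept, median 4.38, rescaled 4.52, camera adjusted p = 7.03e-09, or 0.175 by estimated correlation), with the ribonuclease Ear1 (chromosome 14, 43818765 to 43875517) at 14.9 ± 0.175 and 1510 ± 139 (6.58 ± 0.84, rescaled 6.83, limma adjusted p = 2.01e-04). All 6 B cell genes rose (6 adjusted over the list alone, 4 kept, median 2.76, rescaled 2.86, camera adjusted p = 1.75e-07, or 0.181 by estimated correlation). Class II genes rose for 8 of 9 (8 adjusted over the list alone, 4 kept, median 2.24, rescaled 2.31, camera adjusted p = 1.04e-07, or 0.181 by estimated correlation). The cell cycle fell for 21 of 26 genes, and 7 after rescaling (24 adjusted over the list alone, none kept, median -1.43, rescaled -1.17, camera adjusted p = 2.10e-07, or 0.390 by estimated correlation). Of 14 epithelial identity genes, 9 fell (11 adjusted over the list alone, 2 kept, median -1.46, rescaled -1.20, camera adjusted p = 1.57e-04, or 0.389 by estimated correlation). Epcam went from 35.2 ± 13.5 to 4.89 ± 2.16. Without immune P7 replicate 2, Epcam lost its call (limma adjusted p = 0.0538).

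Atp6v0d2 (5.95 ± 0.45, rescaled 6.01), Gpnmb (5.16 ± 0.72, rescaled 5.32), the transcription factor Bhlhe41 (4.46 ± 0.57, rescaled 4.66), the interleukin 1 receptor antagonist Il1rn (4.44 ± 0.46, rescaled 4.66) and osteopontin, Spp1 (4.39 ± 0.70, rescaled 4.59), rose most over these ages. Cldn6 (-5.32 ± 0.66, rescaled -5.06), Hif3a (-5.18 ± 0.32, rescaled -4.93), Fmod (-4.67 ± 0.45, rescaled -4.44) and Magee2 (-3.80 ± 0.35, rescaled -3.55) fell most, and Hba-x went from 51.0 ± 63.3 to a listed 0. Limma called 1004 genes higher and 1803 lower, and 1618 and 931 after rescaling. Leave-one-out fits called 661 to 1922 genes, against 2807.

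From P7 to P28, immune libraries lost stefin, mast cell and endothelial transcripts. The cysteine protease inhibitor Stfa1 (chromosome 16, 36276951 to 36285373) fell from 69.4 ± 38.3 to 0.875 ± 0.362 (-5.13 ± 0.26, rescaled -5.06, limma adjusted p = 2.43e-08), with Stfa2 (-6.35 ± 0.39, rescaled -6.26), Stfa3 (-5.22 ± 0.26, rescaled -5.25), BC100530 (-4.99 ± 0.26, rescaled -4.94) and Sox18 (-4.62 ± 0.50, rescaled -4.55). Of 6 mast cell genes, 5 fell (6 adjusted over the list alone, 3 kept, median -2.42, rescaled -2.35, camera adjusted p = 7.95e-07, or 0.12 by estimated correlation). The protease Mcpt4 went from 49.6 ± 27.9 to a listed 0; Kit lost its call without immune P7 replicate 1 (limma adjusted p = 0.1). Of 14 endothelial identity genes, 13 fell (14 adjusted over the list alone, 10 kept, median -2.59, rescaled -2.56, camera adjusted p = 4.68e-10, or 0.164 by estimated correlation), and Pecam1 fell by 1.53 ± 0.46 but lost its call without any 1 of the 4 libraries (limma adjusted p up to 0.172).

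Growth genes fell for 11 of 13 (11 adjusted over the list alone, 6 kept, median -2.01, rescaled -2.02, camera adjusted p = 2.03e-08, or 0.0129 by estimated correlation). Of 7 natural killer cell genes, 5 rose (7 adjusted over the list alone, 1 kept, median 1.18, rescaled 1.32, camera adjusted p = 2.03e-08, or 0.12 by estimated correlation). The granzyme Gzma went from 11.7 ± 1.07 to 71.0 ± 28.5, but lost its call without immune P7 replicate 2 (limma adjusted p = 0.0615), as did Klrb1c and Prf1 without replicate 1 (limma adjusted p = 0.0658 and 0.068). Of 10 T cell genes, only the kinase Lck rose (6 adjusted over the list alone, none kept, median 2.20, rescaled 2.39, camera adjusted p = 2.11e-06, or 0.210 by estimated correlation). The list mean of 26 cell cycle genes was 5.37 and 3.62 in immune P28 replicates 1 and 2, and 3.92 and 3.60 at P7. No cell cycle gene passed (none adjusted over the list alone, median 0.76, rescaled 0.93, camera adjusted p = 4.6e-09, or 0.253 by estimated correlation), but Ccna2, Mki67, Pcna and Top2a did without immune P28 replicate 2 (limma adjusted p = 0.00507, 0.0241, 0.00224 and 0.00138), and Pcna with a block by replicate number (limma adjusted p = 0.0428). Cd8b1 (3.21 ± 0.78, rescaled 3.40), the histones Hist2h2bb (2.67 ± 0.84, rescaled 2.86) and Hist1h4c (2.48 ± 0.70, rescaled 2.67), Fabp1 (2.55 ± 0.56, rescaled 2.75) and the T cell adaptor Sit1 (2.32 ± 0.70, rescaled 2.50) rose most. Without immune P28 replicate 1, the calls of Lck, Cd8b1, Hist2h2bb, Hist1h4c and Sit1 ended (limma adjusted p = 0.452, 0.216, 0.542, 0.362 and 0.473), and that of Fabp1 ended without immune P7 replicate 2 (limma adjusted p = 0.111). Limma called 161 genes higher and 1536 lower, and 337 and 1348 after rescaling. The count of 1697 was 719 and 4719 without immune P28 replicates 1 and 2.

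**Figure D3:**
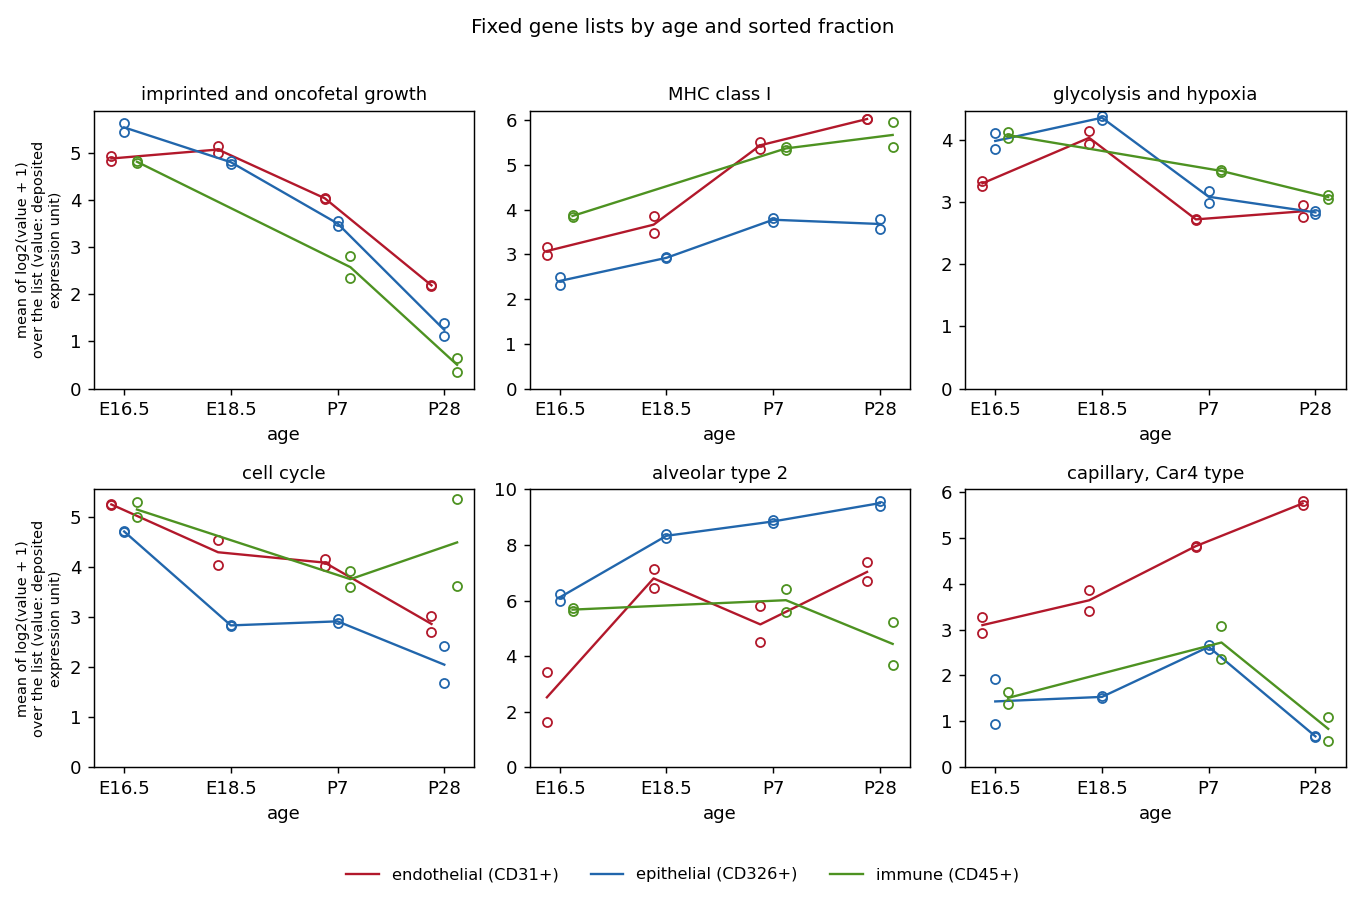
Each of 6 panels plots, against age, the mean of log2(value + 1) over the genes of a list, in the deposited signal unit; circles are libraries, lines join group means and colours mark the fraction. Growth genes fell in every fraction, and glycolysis and hypoxia genes fell between E18.5 and P7 in endothelial and epithelial libraries.

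The same genes changed from E16.5 to P28 in all 3 fractions more often than independent lists would give. Higher in all 3 were 65 genes, against 5 for independent lists, and lower were 695 against 231; after rescaling the counts were 234 against 39 and 229 against 30. The higher genes included the epithelial genes Scgb1a1 (6.88, 9.33 and 4.12 log2 units in endothelial, epithelial and immune cells), Scgb3a1, Lyz1 and Tppp3, with Chil1 and Cox6a2. Also among them were H2-K1, H2-D1, B2m and Psmb8 of the class I pathway, the class II genes H2-Aa, H2-Ab1, H2-Eb1 and Cd74, and Isg15, Ifit3 and Irf7. All 13 growth genes were lower in all 3 fractions, as were Cldn6, Mdk, Hif3a and Slc2a1. Under both scalings, 64 genes were higher and 229 lower in all 3. No library was shared between these comparisons, but the fractions came from the same pools and each held transcripts of the others. The total of 760 was 409 without immune E16.5 replicate 2 and 1398 without immune P28 replicate 1, the range of all such fits.

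The last comparisons asked whether the change from E16.5 to P28 differed between fractions. Endothelial minus epithelial cells gave 3880 genes (3675 higher, 205 lower), and 1294 (729 and 565) after rescaling, since the median of all genes was 0.60 as deposited and 0.02 rescaled. Immune minus endothelial cells gave 2856 genes (513 and 2343, rescaled 926 and 1938, median -0.25), and immune minus epithelial cells 2700 (1845 and 855, rescaled 799 and 1687, median 0.34). Of 34 lists, 18, 25 and 19 passed in these comparisons, and none with an estimated correlation. Leave-one-out fits gave 2086 to 3021, 2016 to 4429 and 1086 to 3866 genes.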

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

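No group held 4 or more libraries, so no library was tested as lying far from its group. The tests of epithelial transcripts in the endothelial fraction and of Xist were chosen only after their results were seen, as was the choice of lists. Of the lists that passed under both scalings in these comparisons (12, 24 and 15), those given are the ones described in both cell types (2, 3 and 1).

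Between endothelial and epithelial cells, the change from E16.5 to P28 differed for 3880 genes by limma's interaction test (1294 rescaled). Alveolar type 1 genes differed by a median of 2.66 (rescaled 1.74, camera adjusted p = 0.00209) and MHC class I genes by 1.69 (rescaled 1.19, camera adjusted p = 0.0107). With an estimated correlation, adjusted p = 0.484 and 0.475. The endothelial change lay above the epithelial one for Ccl21c (7.72, all endothelial, rescaled 7.63, limma adjusted p = 0.0238), Cytl1 (7.16, rescaled 6.70), Prelp (5.81, rescaled 4.99), Fmod (5.80, rescaled 5.30), Sema3c (5.68, rescaled 5.13) and Epcam (2.08, rescaled 1.10, limma adjusted p = 0.0417, or 0.390 rescaled). It was further downward for Kcnj2 (-4.29, rescaled -5.17), Adam19 (-3.98, rescaled -4.73), Cox6a2 (-3.78, rescaled -4.57, epithelial E16.5 listed at 0), Rgcc (-3.57, rescaled -4.33) and Prnd (-3.44, rescaled -4.06, limma adjusted p = 0.0212). Calls ended for Ccl21c without endothelial P28 replicate 2 (limma adjusted p = 0.0683), for Epcam without endothelial E16.5 replicate 2 (limma adjusted p = 0.194) and for Prnd without epithelial E16.5 replicate 2 (limma adjusted p = 0.0868).

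Between immune and endothelial cells, 2856 genes differed (2864 rescaled). Epithelial identity genes differed by a median of -4.15 (rescaled -3.88, camera adjusted p = 2.24e-08), imprinted and oncofetal genes by -1.73 (rescaled -1.64, camera adjusted p = 0.0275) and cell cycle genes by 1.69 (rescaled 1.98, camera adjusted p = 3.92e-13). With an estimated correlation, adjusted p = 0.219, 0.219 and 0.222. The cell cycle mean was 5.37 in immune P28 replicate 1, where T cell genes were high, and 3.62 in replicate 2, against 5.01 and 5.30 at E16.5. The immune change lay above the endothelial one for Hist1h2bk (5.89, rescaled 6.15, limma adjusted p = 0.0163), Dusp2 (4.76, rescaled 5.00), Fabp1 (4.56, rescaled 4.82), Atp6v0d2 (4.41, rescaled 4.66), Hist1h3b (4.29, rescaled 4.57) and Ptprc (1.78, rescaled 2.22). It lay below the endothelial one for Ccl21c (-7.72, all endothelial, rescaled -7.63, limma adjusted p = 0.0266) and the epithelial genes Clic3 (-7.42, rescaled -7.10), Sfta2 (-7.38, rescaled -7.10), Muc1 (-7.37, rescaled -7.05), Sec14l3 (-6.92, rescaled -6.57) and Epcam (-4.22, rescaled -3.90). Without endothelial P28 replicate 2, Ccl21c and Hist1h2bk lost their call (limma adjusted p = 0.0815 and 0.0890).

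Between immune and epithelial cells, 2700 genes differed (2486 rescaled). Cell cycle genes differed by a median of 2.04 (rescaled 1.60, camera adjusted p = 1.80e-06; adjusted p = 0.473 with an estimated correlation), with the same gap between immune P28 replicates. The immune change lay above the epithelial one for Fabp1 (4.87, rescaled 4.99), Hist1h2ac (4.76, rescaled 4.71, limma adjusted p = 0.0269), the chemokine receptor Cxcr4 (4.58, rescaled 4.33), Il1b (4.56, rescaled 4.82), Hist1h2bf (4.55, rescaled 4.17) and Ptprc (1.95, rescaled 2.34). It was further downward for Lcn2 (-7.99, rescaled -8.49), Chil1 (-6.35, rescaled -6.91), C3 (-5.51, rescaled -5.95), Sfta2 (-5.44, rescaled -6.15), Rnase4 (-5.23, rescaled -5.84) and Epcam (-2.15, rescaled -2.80, limma adjusted p = 0.0468). Without immune E16.5 replicate 1, Hist1h2ac and Epcam lost their call (limma adjusted p = 0.111 and 0.169), and Epcam did with a block by replicate number (limma adjusted p = 0.0527).

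Epithelial cells or their RNA may explain the alveolar type 2 genes of the endothelial fraction. At E18.5, P7 and P28 these genes stood at 0.92 of the share shown by epithelial identity genes, as a median over 6 libraries (0.83 to 1.07). All 13 stayed called when rescaled, but near-equal endothelial factors cannot test for a few abundant genes. For alveolar type 1 genes the quotient was 2.52 (1.54 to 7.25), with 6.77 and 7.25 at P28, above the limit of 4 set for the test, and what keeps their source open is that endothelium makes some of them itself: Cav1 stood at 188 ± 20.9 in P28 endothelial and 10.9 ± 2.59 in epithelial libraries. A sort for CD31 should have removed epithelial cells, and a biological change with age was not tested apart from carry-over.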

How the results depend on the processing

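The alternatives that leave out both T-rich immune libraries, or the genes of the epithelial fraction, were tests chosen only after the data were seen. No called named gene changed direction under any alternative run. With size factors, the side with more calls, higher or lower, switched for endothelial P28 against P7 and E16.5, epithelial E18.5 and P28 against E16.5 and P7 against E18.5, immune P7 against E16.5, endothelial cells against the others and immune minus epithelial change, and other alternatives switched some. Unless construction is named, the cause was not tested.

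Counts moved over 1.5 times as follows. With a pseudocount of 0.1, endothelial P28 against P7 gave 266 genes. With a filter of at least 5, which tests fewer genes, endothelial P28 against P7 gave 361, epithelial P7 against E18.5 385, epithelial P28 against E16.5 4711, the cell type comparisons 4800 (endothelial), 5258 (epithelial) and 4630 (immune), and endothelial minus epithelial change 2560. With size factors, epithelial E18.5 against E16.5 gave 1058, P28 against P7 1120 and P28 against E16.5 4339, endothelial minus epithelial change 1294 and the overlap 463. Fits to 1 cell type gave 140, 353 and 1675 for immune P7 against E16.5, P28 against P7 and P28 against E16.5, and 268 for the overlap. Such fits hold fewer samples and take the spread from that cell type alone. The endothelial and epithelial counts did not move over 1.5 times in them.

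A fold change limit of 1 on the log2 scale lowers counts by construction. It gave 792, 758, 356 and 2009 for the endothelial ages in the order E18.5 against E16.5, P7 against E18.5, P28 against P7 and P28 against E16.5. The epithelial counts were 773, 381, 1089 and 4101, the immune counts 1415, 1117 and 1963, and the cell type counts 2165, 2202 and 2051. Without both libraries described with another age, endothelial E18.5 and P28 against E16.5 gave 249 and 1828, epithelial E18.5 against E16.5 gave 252 and the overlap 330. Without both T-rich immune libraries, immune P28 against P7 gave 774. Without the 853 genes of the epithelial fraction, endothelial E18.5 against E16.5 gave 739 (312 higher and 427 lower).

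Lists that passed with the preset correlation mostly failed with an estimated correlation between genes. In the order above, those passing were 0, 4, 1 and 3 for endothelial, 0, 2, 1 and 2 for epithelial and 2, 1 and 4 for immune ages, and 0 for each cell type and interaction comparison.

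With each library left out in turn, where a lone library is assumed to vary like the others, counts ranged as follows. Endothelial ages gave 314 to 1260, 583 to 1075, 166 to 264 and 1976 to 2456. Epithelial ages gave 409 to 667, 197 to 396, 579 to 3386 and 5494 to 6293. Immune ages gave 661 to 1922, 719 to 4719 and 2523 to 4574. Cell types gave 6616 to 7909, 7283 to 8492 and 6467 to 7494, interactions 2086 to 3021, 2016 to 4429 and 1086 to 3866, and the overlap 409 to 1398.

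Of calls for named genes, 3189 were the same, 324 weaker and 17 stronger with a library left out. Size factors weakened 21, a pseudocount of 0.1 weakened 57, no filter weakened 43 and fits to 1 cell type weakened 85. No count moved over 1.5 times with a replicate block by number or pool. Block by number weakened 3 genes and gave 1 a call, block by pool 2 and 2 (random) or none and 1 (fixed). Size factors, a pseudocount of 0.1 and a filter of at least 5 each gave 1 gene a call. Pairing by pool showed r of 0.57, 0.34 and 0.41 between cell types at P7 across genes, 0.15 to 0.22 at E16.5 and P28, and 0 at E18.5. Depth was unknown, so what it limits could not be given.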

Other observations

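The Xist test and the lists described here were chosen only after the results were seen; the tests of thymocyte genes, of lost low values and of splits were set first. Mesothelial markers were higher in P28 than in E16.5 endothelial libraries for 4 of 4 genes (4 adjusted over the list alone, 3 kept, median log2 fold change 3.04, camera adjusted p = 0.00227, or 0.275 by estimated correlation). Msln went from 1.48 ± 1.25 to 35.8 ± 22.4 (3.84 ± 0.57, limma adjusted p = 1.83e-04). Of 5 lymphatic markers, 3 were higher (3 adjusted over the list alone, 3 kept, median 0.72, camera adjusted p = 0.0119, or 0.297 by estimated correlation). The chemokine Ccl21a went from 82.4 ± 11.8 to 894 ± 250 (3.40 ± 0.65, limma adjusted p = 0.0013).

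T cell genes were far higher in immune E16.5 replicate 2 and immune P28 replicate 1 than in the other replicate. Immature thymocyte genes were higher there by a median of 2.15 (MAD 1.37, 13 of 18 genes over 1) and 3.41 (MAD 1.38, 15 of 18), with Rag2 at 61.1 against 0.931 and 95.9 against 0.114. Thymocytes or their RNA may have been in both libraries, and a sort for CD45 would not remove them. The values argue against more mature T cells, as in blood, as the whole cause: these genes were then to stay within 1 log2 unit, and mature T cell genes differed by a median of 0.61 (MAD 0.35) and -0.56 (MAD 0.89). Of the 18 genes, 6 stood at 1 or more in the other replicate in each case. No other biological explanation was tested.

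Y-linked genes summed to 0.296 in immune E16.5 replicate 1, against 8.44 and 8.83 in the endothelial and epithelial libraries of the same pool. Of 2867 other genes at 1 to 5 in those libraries, 4 (0.14%) were under 0.1 of their mean, which argues against lost low values. The Xist quotient of 1.23 cannot tell cells of other embryos from female cells of this pool, and a wrong pool name stays open. No biological explanation was tested.

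The cell type comparisons were set beside other splits of the libraries. Of 100 splits of the libraries into cell types within pools, 1 gave as many genes, the real one, with 7380, 8096 and 7139 genes for endothelial, epithelial and immune cells. The highest other split gave 5537, 4298 and 4608.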
